A study of Saccharomyces cerevisiae with 151 samples.

How the data were processed

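RNA of Saccharomyces cerevisiae BY4741 and of strains derived from it by deletion of transcription factor genes was measured on 151 single-colour Affymetrix yeast arrays. Per the labels' protocols, cells grew at 28 °C in synthetic complete medium to an OD600 of 0.5 before 100 mM 3-aminotriazole was added and total RNA was labelled with biotin. Each array's strain, time and replicate number came from its labels. Among the 151 arrays 0 pairs held identical values.

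The deposited values are probe set intensity on a linear scale, summarised by the authors with MAS5, per the submitters' processing notes; the MAS5 version is not given in the sources used here. By their values the arrays have different scales: in 78 the 2% trimmed mean was 499.7, the mark of scaling to a common target, and in the other 73 it ran from 22.38 to 104.3 (median 62.36). The unscaled arrays were replicate 3 of gcn4 and leu3 and every array of the double deletions and of met31. The design fixed before the data were examined took the values as deposited and assumed 1 scale. Here each array was instead multiplied by 1 factor that set its 2% trimmed mean to 500, a departure chosen after the scales were seen, and results from the deposited values without rescaling stand among the alternatives. All double deletion arrays were unscaled and all WT arrays scaled, so a comparison of these strains also compares deposited scales, and the 2 cannot be told apart. A block for the scaling class rests on replicate 3 of gcn4 and leu3 and takes all unscaled arrays as 1 batch, although their small RNA signals differed (medians of 459 on unscaled arrays of gcn4 and leu3 and 88.4 on those of double deletions and met31).

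The table holds 9335 probe sets. Of the 6832 with an entry in the platform annotation, 6504 name 1 gene, each matched to a current symbol through its Entrez ID, and 328 name several; 2503 have no gene and were not named. For the 315 genes with several probe sets, the one with the highest mean log2 value was used, taking first those whose identifier marks no cross-hybridisation; 248 genes were tested on probe sets marked as shared. Genes named from shared probe sets may include signal of near-identical copies. A gene was kept if its signal was above the array's floor in at least 2 of 3 arrays, or 1 of 2, of at least 1 group with replicates, where the floor is the 20th percentile of the array's probe sets (13.01 to 31.46, median 21.34, after rescaling). This left 5611 of 5656 genes and removed 45. Changes were computed on log2(signal + 16), which understates the change of genes with low signals.

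Tests were made with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), with 1 coefficient per group and all 145 arrays of the 7 strains with replicates in 1 fit, so that all groups shared 1 estimate of the spread (95 residual and 9.07 prior degrees of freedom). P-values were adjusted by the Benjamini-Hochberg method over the 5611 genes of each contrast, two-sided, and called at 0.05. The contrasts were each WT time against 0 min, with an F-test over all of them. For each deletion strain they were 0 min against WT at 0 min, 60 min against its own 0 min, and the difference between that change and the change in WT. For each double deletion, the sum of both single deletions was set against the double at 60 min, the last time shared by the strains with replicates. The median SE of a contrast was 0.336 for 3 against 3 arrays, and for the differences of 4 groups it was 0.475 or 0.504.

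Gene lists (34, fixed before the data were examined) were tested with limma's camera with a preset correlation of 0.01 between genes. Its p-values, adjusted over the lists of a contrast, are those given unless an estimated correlation is named, which made fewer calls. Members that passed limma's test are counted after adjustment over all genes, and again over the list alone. Lists are described where they held with the estimated one, and Leu3 targets and nitrogen catabolite repressed genes also in strains lacking LEU3 or GAT1. WT lists at 60 min that lost their call are also given. List tests of WT at times other than 60 min, differences between strains at 20 min and deletion effects in other strain backgrounds were added after results had been seen.

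The genes named were chosen by a rule fixed beforehand. It takes the deleted genes and auxotrophic markers, and the 10 largest rises and 10 largest falls in WT at 60 min. In other comparisons it takes the 5 largest of each, among called genes whose replicates did not overlap (for differences of responses and sums, called genes), on probe sets of 1 gene. It adds up to 4 members with the largest change of each list that passed or belongs to the deleted factor, and the mating-type genes. Other genes are said to be chosen after their values were seen. The strain check was changed after the data were seen. With the first criterion, a reading below the lowest WT array, 118 of 178 readings of deleted genes were low, because single WT arrays read near 0; with the criterion used, below the WT median divided by 3, 177 were.

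Near-zero readings were defined after the data were seen, as values below the lowest value of the same probe set on every other array of the strain divided by 10, where that lowest value was above 200; 6 arrays had more than 10 of them. Whether replicate numbers pair arrays was checked by correlating the deviations of same-numbered arrays from their group means. The pairing comes only from the numbers in the labels. Every one of 3 pairs was over 0.1 for WT at 10 min (0.25 to 0.29), 20 min (0.17 to 0.26) and 90 min (0.12 to 0.29), for the responses of leu3 (0.20 to 0.29) and gcn4leu3 (0.19 to 0.27), and for the baseline of gcn4leu3 (0.15 to 0.38).

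Tests were first run on simulated data with the means and spread of the real genes, 100 of the 5611 changed 2-fold and 100 4-fold. In WT at 60 min 56 of the first and 92 of the second were recovered, with 8 false calls. For the baseline of gcn4 the numbers were 39, 94 and 7, for the gcn4 response 30, 88 and 4, and for the response difference of gcn4leu3 13, 74 and 2. In each a shifted list and 0 others were called, but no list of correlated genes was simulated. Alternatives tried were quantile normalization, median centring, other pseudocounts and filters, all probe sets, array weights, fits without the trend or of only the strains compared, replicate blocks, and the omission of each array in turn. Alternatives for 419 values of named genes and 102 of lists were limited to results chosen after the tests. Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.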

Results

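Expression was measured on 151 yeast arrays in BY4741, a haploid MATa strain, grown in synthetic complete medium and given 100 mM 3-aminotriazole (3AT). 3AT blocks the HIS3 enzyme and is used to starve cells of histidine. Here HIS3 is partly deleted, the medium was complete, and starvation was not tested. The wild type (WT) and strains lacking GCN4, LEU3 or GAT1 were sampled at 0, 10, 20, 30, 45, 60, 90 and 120 min, and the double deletions gat1gcn4, gcn4leu3 and gat1leu3 at 0 to 60 min. Gcn4 activates amino acid biosynthesis genes, Leu3 regulates branched-chain amino acid synthesis, and Gat1 activates genes under nitrogen catabolite repression. Of the 50 groups with replicates, 45 had 3 arrays, and 5 had 2 (gat1 at 20 min, gat1gcn4 at 0 and 45 min, gat1leu3 at 45 min and gcn4 at 60 min). A strain lacking MET31, a regulator of sulfur genes, had 1 array at each of 6 times and entered no test. The number of arrays limits the precision. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Changes are given on the log2(signal + 16) scale with their SE from limma over 5611 genes.

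Each deleted gene was low in nearly every array of its strains. The GCN4 signal had a median of 6750 in WT (range 5370 to 8860), 259 in gcn4 (35.2 to 2290), 27.1 in gat1gcn4 and 17.9 in gcn4leu3. LEU3 had a median of 117 in WT, 6.29 in leu3, 5.68 in gcn4leu3 and 4.91 in gat1leu3. GAT1 had a median of 138 in WT, 6.86 in gat1, 7.26 in gat1gcn4 and 8.5 in gat1leu3, and MET31 had 450 in WT and 8.37 in met31. Of 178 readings of a deleted gene in its own strain, 177 lay below the WT median divided by 3, as did 4 of 426 readings in strains with the gene. The exception was the library labelled gcn4 90 min replicate 3 (GCN4 signal 2290, at most 434 on the other gcn4 arrays). LEU3 read 1.05 on the library labelled WT 30 min replicate 2. Among the auxotrophic markers, LEU2 (16 to 33.6) and MET17 (4.96 to 18.8) had low strain medians. URA3 had a median of 103 in gat1gcn4, 667 in gcn4leu3 and 508 in gat1leu3, and at most 3.97 in the other strains. In gat1gcn4 it read 43.5 to 106 in replicates 1 and 2 and 231 to 1150 in replicate 3 (cause not tested). HIS3 medians ran from 1570 to 3530. The HIS3 probe set checks nothing if it lies outside the deleted part. The a-specific pheromone gene MFA1 had a median signal of 4930 in WT and 21900 in gcn4.

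**Figure D1:**
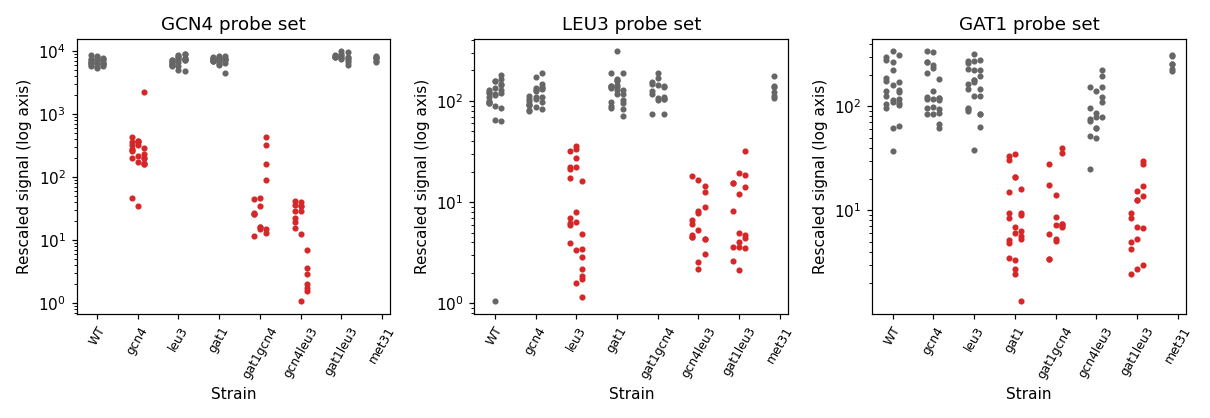
Signal of GCN4, LEU3 and GAT1 (rescaled array units, log axis) on each array, by strain, with strains deleted for that gene in red and the others in grey; each point is 1 array. Nearly all red points lie below the grey ones; the GCN4 reading of 2290 in gcn4 stands above the other red points, and the LEU3 reading of 1.05 in WT below the other grey ones.

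From 10 to 30 min oxidative stress genes rose in WT, joined by iron genes at 20 and 30 min. SRX1, which encodes sulfiredoxin, rose by 4.72 ± 0.48 (SE) at 10 min and by 5.36 ± 0.48 at 20 min, from a signal of 118 ± 36.3 to 5490 ± 1500 (SD, n = 3 each, limma adjusted p = 9.1e-16). Other oxidative stress genes rose at 20 min, among them TRR1 (thioredoxin reductase, 1.82 ± 0.22), GPX2 (2.50 ± 0.45) and TSA2 (peroxiredoxin, 2.08 ± 0.45). In total 6 of 20 members of that list rose (9 adjusted over the list alone, median 0.56, camera adjusted p = 3.4e-17). Of 21 iron regulon genes, 10 rose at 20 min (11 adjusted over the list alone, median 1.29, camera adjusted p = 3.2e-23). Among them were HMX1, a heme oxygenase (3.92 ± 0.55), and TIS11 (3.67 ± 0.60). At 30 min 9 iron genes rose (13 adjusted over the list alone), and FIT2 was up by 4.48 ± 0.74. The carnitine genes YAT2 (3.30 ± 0.44 at 20 min) and CRC1 (3.56 ± 0.50 at 30 min) and the nitroreductase-like gene FRM2 (4.33 ± 0.63 at 20 min) also rose. HXT6, a glucose transporter, rose by 2.76 ± 0.50 at 10 min. The largest falls at 20 min were in EEB1, an ethyl ester synthase (-3.35 ± 0.45), STP4 (-2.83 ± 0.55), ECM13 (-2.58 ± 0.42), TPO1, a polyamine exporter (-2.26 ± 0.43), and HAP4, an activator of respiratory genes (-2.23 ± 0.34).

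In all, 36 genes rose and 35 fell in WT at 10 min, 69 and 56 at 20 min, and 53 and 30 at 30 min. With median centring the splits were 48 and 23 at 10 min and 92 and 37 at 20 min. At 10 min the oxidative stress list had a median of 0.36, with 3 of 20 genes up (3 adjusted over the list alone, camera adjusted p = 7.5e-08). Of the 21 iron genes 3 rose at 10 min, HMX1, TIS11 and MRS4 (8 adjusted over the list alone, median 0.44), but the list's call was lost (adjusted p = 0.23 with an estimated correlation). At 30 min 5 of 20 oxidative stress genes (5 adjusted over the list alone, median 0.56, camera adjusted p = 1.2e-13) and 2 of 13 phosphate genes, PHO84 and VTC3, rose (3 adjusted over the list alone, median 0.30, camera adjusted p = 0.0014). The serine, threonine and homoserine genes had a median of 0.54 at 20 min, and 2 of 10, SER3 and SER33, rose (4 adjusted over the list alone, camera adjusted p = 6.5e-06). With the replicate number as a block the counts were 140 at 10 min and 300 at 20 min. Leaving out 1 array at a time gave 26 to 42 genes at 10 min, 58 to 126 at 20 min and 44 to 226 at 30 min, the last without replicate 3 of that time. The median over all genes was -0.118 at 20 min. The 30 min group holds the library in which LEU3 read 1.05.

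At 60 min sulfur and methionine genes were the leading rise in WT, while the permease genes AGP1, GAP1 and MEP3 and 2 of 7 arginine genes fell. MET2, homoserine acetyltransferase, rose by 3.62 ± 0.82 from 44.2 ± 12.5 to 714 ± 32.5 (n = 3 each, limma adjusted p = 0.006). MET14, adenylylsulfate kinase, rose by 3.42 ± 0.54 from 294 ± 75 to 3330 ± 930 (adjusted p = 9.2e-06). MMP1 (S-methylmethionine permease, 3.13 ± 0.50), MHT1 (2.80 ± 0.43), MET6 (methionine synthase, 2.34 ± 0.60) and MUP1 (methionine permease, 1.95 ± 0.44) rose with them. Of the 22 sulfur and methionine genes, 5 rose (12 adjusted over the list alone, median 1.15, camera adjusted p = 1.5e-26). FIT2 (2.89 ± 0.74), BIO2 (biotin synthase, 2.21 ± 0.40), REE1 (2.11 ± 0.46) and PYC1 (pyruvate carboxylase, 1.99 ± 0.51) complete the 10 largest rises. Among amino acid and ammonium permeases, AGP1 fell from 1730 ± 54.2 to 236 ± 99.9 (-2.87 ± 0.40, adjusted p = 6.3e-07), GAP1 by 2.75 ± 0.61 and MEP3 by 1.96 ± 0.44. Of 22 nitrogen catabolite repressed genes 5 fell (6 adjusted over the list alone, median -0.43, camera adjusted p = 9.9e-07). YNL134C (-2.86 ± 0.52), EEB1 (-2.81 ± 0.45), ECM13 (-2.62 ± 0.42), STP4 (-2.44 ± 0.55), SER3 (-2.33 ± 0.60), ARO3 (-2.26 ± 0.39), PIC2 (-2.25 ± 0.48) and PDR12, a weak acid exporter (-2.10 ± 0.36), also fell.

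The arginine biosynthesis list had a median of -1.38 at 60 min, with 2 of 7 genes falling (5 adjusted over the list alone, camera adjusted p = 3.6e-10), ARG7 by 1.84 ± 0.41 and ARG1 by 1.62 ± 0.36. The glutamate, glutamine and asparagine list (median -0.66, 1 of 6 fell, GLT1, 3 adjusted over the list alone) and the aromatic list (median -0.64, 1 of 14 fell, ARO3, 2 adjusted over the list alone) were also lower, with camera adjusted p = 0.00076 and 7.3e-05. The retrograde response list was higher (median 0.49, PYC1 and DLD3 of 7 rose, 3 adjusted over the list alone, camera adjusted p = 1e-04). In total 13 of 34 lists passed camera's test with the preset correlation of 0.01, and 6 with an estimated correlation, those described so far. The call was lost, with adjusted p = 0.069, 0.28, 0.19, 0.099, 0.19, 0.24 and 0.19 with an estimated correlation, for 7 lists. These were lysine (median -0.81, none of 9 genes passed, 3 adjusted over the list alone), histidine (-0.47, none of 6, 1), permeases (-0.43, 1 rose and 1 fell of 13, 4), heat shock chaperones (0.58, none of 20, 1), oxidative stress (0.32, none of 20, 2), iron (0.39, 1 of 21, 2) and proteasome genes (0.29, 0 of 32 by limma, 0).

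Over the full WT series 405 genes varied with time by limma's F-test. At 60 min 15 rose and 31 fell, at 45 min 26 and 33, at 90 min 16 and 26, and at 120 min 17 and 53. At 45 min FIT2 was up by 4.32 ± 0.74 and HSP82, the Hsp90 chaperone, by 2.67 ± 0.67, and AGP1 (-3.0 ± 0.40) and MEP2 (-2.49 ± 0.48) were down. Then 3 of 7 arginine genes fell (6 adjusted over the list alone, median -1.26, camera adjusted p = 9.7e-10), ARG3 by 1.96 ± 0.54, and 1 of 6 glutamate genes, GLT1 (3, median -0.69, 0.0025). At 45 min 3 of 22 sulfur genes (8 adjusted over the list alone, median 0.82), 2 of 21 iron genes (8, median 0.69), 4 of 20 oxidative stress genes (6, median 0.33), 2 of 7 retrograde genes (3, median 0.47) and HSP82 of 20 chaperone genes (6, median 0.53) rose. The proteasome list was higher with none of 32 genes passing (0 adjusted over the list alone, median 0.47), and camera's adjusted p for these 6 lists ran from 1e-15 to 0.00036. MET2 (3.35 ± 0.82) and MET14 (3.23 ± 0.54) were still up at 90 min, when 5 of 22 sulfur genes rose (11 adjusted over the list alone, median 1.11, camera adjusted p = 1e-20). Arginine (1 of 7 fell, 5 adjusted over the list alone, median -1.09, camera adjusted p = 1.6e-07) and glutamate genes (1 of 6, 1, median -0.55, 0.0034) were lower at 90 min. At 120 min the copper transporter CTR1 (2.56 ± 0.65), the metal reductase FRE1 (2.15 ± 0.47), IZH4 (2.60 ± 0.63) and BIO2 (2.47 ± 0.40) were up, and YNL134C (-3.26 ± 0.52) and TDH1 (-2.63 ± 0.60) were down. The replicate block gave 100 genes at 90 min. Median centring gave splits of 30 up and 27 down at 60 min, 40 and 28 at 45 min, 21 and 22 at 90 min and 29 and 40 at 120 min. Omitting 1 array, given in brackets by time and replicate, gave 27 (0 min 2) to 40 genes at 45 min, 23 (0 min 1) to 33 at 60 min, 12 (90 min 2) to 26 at 90 min and 24 (0 min 2) to 70 at 120 min.

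**Figure D2:**
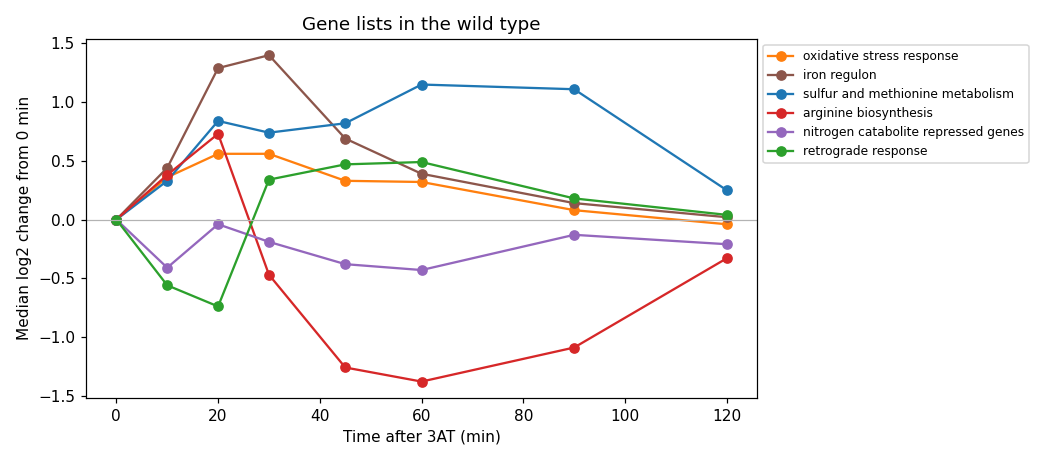
Median log2 change from 0 min (y axis) of 6 gene lists in WT against time after 3AT in min (x axis); points are medians over the members of a list, from groups of 3 arrays. The iron list peaks at 1.40 at 30 min, the sulfur list at 1.15 at 60 min, and the arginine list is lowest at -1.38 at 60 min.

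Before 3AT gcn4 had low amino acid and vitamin B6 genes and, like leu3, high stress genes. Culture state was not tested. SNZ1 and SNO1, the vitamin B6 pair, fell by 3.85 ± 0.38 (3940 ± 130 in WT to 273 ± 122 in gcn4, n = 3 each, limma adjusted p = 7.6e-14) and 2.99 ± 0.42 (both, camera adjusted p = 1.5e-11, 2 adjusted over the list alone). ARG4, argininosuccinate lyase, fell from 8490 ± 227 to 999 ± 130 (-3.07 ± 0.38, adjusted p = 2.7e-09), and ARO5 (-3.21 ± 0.41) and the alcohol dehydrogenase gene ADH5 (-2.74 ± 0.53) were the other large falls. Of 28 general stress genes 21 rose (26 adjusted over the list alone, median 2.26, camera adjusted p = 3.1e-38), led by DDR2 (4.65 ± 0.87), the cell wall glycoprotein gene YGP1 (4.19 ± 0.53), HSP12 (4.13 ± 0.82) and SPI1 (3.75 ± 0.59). FMP16 (3.99 ± 0.63) and EGO4 (3.99 ± 0.57) rose as much.

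Of the amino acid lists in gcn4, the aromatic one lost 7 of 14 genes (8 adjusted over the list alone, median -0.82), branched-chain 4 of 10 (8, median -1.25, LEU9 -1.97 ± 0.33, ILV6 -1.80 ± 0.31), histidine 4 of 6 (5, median -1.01), arginine 3 of 7 (3, median -0.87), and lysine 3 of 9 (5, median -1.18). Serine, threonine and homoserine genes lost 3 of 10 (6 adjusted over the list alone, median -0.59), HOM3 among them (-1.82 ± 0.30). Purine biosynthesis had 4 of 10 falling (7 adjusted over the list alone, median -0.82), aminoacyl-tRNA synthetases 2 of 18 (4, median -0.55), Leu3 targets 1 of 7 (5, median -1.15) and glutamate, glutamine and asparagine 1 of 6 (2, median -0.66). Citric acid cycle and respiratory genes were higher as a list (2 of 31 rose, 4 adjusted over the list alone, median 0.67), with a median of -0.45 in the deposited values without rescaling. There the unscaled gcn4 replicate 3, with a trimmed mean of 39.21, lowers every gene, so that sign decides nothing. Camera's adjusted p for these 11 lists lay between 3.6e-09 and 0.011, and each kept its call with an estimated correlation. In all 159 genes rose and 113 fell. With scaled arrays alone the count was 1035, and 1-array omissions gave 101 to 672, the lowest without gcn4 0 min replicate 2 and the highest without replicate 3.

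The leu3 and gat1 strains differed from WT at fewer genes before 3AT. In leu3 the mitochondrial carrier gene OAC1 fell from 4800 ± 336 to 666 ± 292 (-2.90 ± 0.30, n = 3 each, limma adjusted p = 1.2e-12). LEU1, isopropylmalate isomerase, fell by 2.64 ± 0.46 and the aminotransferase gene BAT1 by 2.16 ± 0.37. These are the 3 of 7 Leu3 targets that fell (3 adjusted over the list alone, median -0.60, camera adjusted p = 3.5e-14). LEU1 and BAT1 are the 2 of 10 branched-chain genes that did (2 adjusted over the list alone, median -0.63, camera adjusted p = 2e-07). The zinc regulon genes ZRT1, a zinc transporter (-2.42 ± 0.46), and ZPS1 (-2.38 ± 0.46) fell, 2 of 6 in that list (2 adjusted over the list alone, median -0.56, camera adjusted p = 4.7e-06). YGP1 (2.99 ± 0.53), RTC3 (2.61 ± 0.60) and RIE1 (1.68 ± 0.40) rose, and the stress list was higher (1 of 28 rose, 16 adjusted over the list alone, median 1.15, camera adjusted p = 1e-26). In gat1, YGP1 rose by 2.81 ± 0.53, and ZRT1 (-2.51 ± 0.46), COS12 (-2.03 ± 0.37) and YHB1, a flavohemoglobin (-1.78 ± 0.36), fell. The zinc list had 1 of 6 falling in gat1 (2 adjusted over the list alone, median -0.26, camera adjusted p = 0.0001).

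None of the 22 nitrogen catabolite repressed genes passed the test in gat1 (1 adjusted over the list alone, median -0.24). Their camera adjusted p was 0.032, and adjusted p = 0.67 with an estimated correlation; the ammonium permease gene MEP2 had the largest value, -1.74 ± 0.48 (limma adjusted p = 0.23). The other genes that fell in leu3 were YAR068W (-2.32 ± 0.49) and the deleted LEU3 (-2.56 ± 0.37, limma adjusted p = 6.3e-07), and in gat1 the deleted GAT1 (-3.99 ± 0.41, adjusted p = 1.7e-12). In all, 3 genes rose and 7 fell in leu3, and 1 rose and 4 fell in gat1. Array quality weights gave 278 and 68 genes, and scaled arrays alone 84 and 29. Omissions of 1 array gave 7 to 16, the highest without leu3 replicate 1, and 3 to 6, the lowest without gat1 replicate 3.

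The double deletions lacking GCN4 had low arginine, histidine, aromatic and vitamin B6 genes before 3AT. ARG4 fell by 3.95 ± 0.38 in gcn4leu3 (8490 ± 227 in WT to 600 ± 303, n = 3 each, limma adjusted p = 3.3e-14). ARG1, argininosuccinate synthase, fell by 3.50 ± 0.40 in gat1gcn4 (10500 ± 1500 to 990 ± 549, n = 3 and 2, adjusted p = 1.1e-10). In both strains 4 of 7 arginine genes fell (5 adjusted over the list alone in gat1gcn4 and 4 in gcn4leu3, medians -2.0 and -1.88, camera adjusted p = 3.3e-11 and 3.4e-14). Of 6 histidine genes 4 fell in gat1gcn4 (4 adjusted over the list alone, median -1.07) and 3 in gcn4leu3 (4, median -0.96). Of 14 aromatic genes 3 fell in each (8 and 10 adjusted over the list alone, medians -0.96 and -0.92). Camera's adjusted p for these lists ran from 2.2e-06 to 3.4e-06. SNZ1 and SNO1 fell in both (2 adjusted over the list alone in each, medians -2.96 and -2.42, camera adjusted p = 1.5e-08 and 8e-08). In gat1gcn4, 2 of 9 lysine (7 adjusted over the list alone, median -1.13), 2 of 10 purine (6, median -0.82) and 2 of 10 serine, threonine and homoserine genes (3, median -0.57) fell, with camera adjusted p = 6.4e-06, 8.2e-08 and 0.0022. Without its 0 min replicate 1 the histidine, lysine and serine lists had medians of -0.60, -0.52 and -0.34 and lost their calls (adjusted p = 0.075, 0.073 and 0.075). In gcn4leu3, HOM3 and HOM2 of the last list fell (3 adjusted over the list alone, median -0.28, camera adjusted p = 0.00012), as did 4 of 10 branched-chain genes (7, median -1.17, 1.9e-13). In gcn4leu3, 3 of 7 Leu3 targets fell (5 adjusted over the list alone, median -1.72, camera adjusted p = 1.9e-13), BAT1 by 3.24 ± 0.37, LEU1 by 3.02 ± 0.46 and OAC1 by 2.47 ± 0.30. DDR2 rose by 4.67 ± 0.98 in gat1gcn4 and 4.15 ± 0.87 in gcn4leu3. Of 28 stress genes 14 rose in gcn4leu3 (23 adjusted over the list alone, median 1.76, camera adjusted p = 3.9e-22), a list whose median is -0.57 in the deposited values without rescaling. The glucose transporter genes HXT4 (4.03 ± 0.63) and HXT6 (3.87 ± 0.50) rose in gcn4leu3. Retrograde genes were lower there (3 of 7 fell, 3 adjusted over the list alone, median -0.86, camera adjusted p = 8.9e-05), among them ACO1, aconitase (-2.23 ± 0.41).

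G1/S genes were lower in gat1gcn4 (2 of 10 fell, 8 adjusted over the list alone, median -1.44, camera adjusted p = 4.9e-09), CDC45 by 3.04 ± 0.40. In gat1leu3, HXT4 (3.03 ± 0.63), HXT6 (2.86 ± 0.50), the phosphate transporter gene PHO84 (2.47 ± 0.59), PRM7 (2.28 ± 0.50) and HXT7 (2.28 ± 0.42) were higher, while in the deposited values HXT6, PHO84, PRM7 and HXT7 had the opposite sign. The tRNA genes YNCM0009C (-3.90 ± 0.64) and YNCA0006C (-3.85 ± 0.62) and the small nuclear RNA gene SNR14 (-3.56 ± 0.62) were lowest in gat1leu3. Of 7 Leu3 targets 4 fell there (4 adjusted over the list alone, median -1.11, camera adjusted p = 0.011, adjusted p = 0.31 with an estimated correlation), GDH1 by 1.77, LEU1 by 1.53, OAC1 by 1.15 and BAT1 by 1.11. Of 22 nitrogen catabolite repressed genes 6 fell in gat1leu3 (8 adjusted over the list alone, median -0.51, camera adjusted p = 0.002, adjusted p = 0.31 with an estimated correlation), GAP1 by 2.72 and DAL3 by 2.34, and none in gat1gcn4 (0, median -0.19, 0.25). With replicate 3 alone at 0 min Leu3 targets had -0.57 (adjusted p = 0.0017), OAC1 -1.95 (0.0044) and the nitrogen list 0.18 (0.77). Both calls were lost without replicate 1 (adjusted p = 0.051 and 0.082), and that of Leu3 targets without replicate 3 (0.094). In all 88 genes rose and 157 fell in gat1gcn4, 108 and 83 in gcn4leu3, and 50 and 326 in gat1leu3, where the median over all genes was -0.118. Median centring gave 91 and 121 in gcn4leu3 and 111 and 214 in gat1leu3, and quantile normalization 89 and 236 in gat1leu3. In double deletions strain and scaling class cannot be told apart. With that class as a block, which takes the unscaled arrays as 1 batch and rests on replicate 3 of gcn4 and leu3, the counts were 525 in gat1gcn4 and 591 in gcn4leu3, and without arrays holding near-zero readings 80 in gat1leu3. Such readings enter 45 of 245 calls in gat1gcn4 and 60 of 376 in gat1leu3. Omitting 1 array gave 100 to 272 genes in gcn4leu3, the ends without 0 min replicates 1 and 3, and 66 to 567 in gat1leu3, without replicates 2 and 3. The 0 min arrays of gat1leu3 stood apart: the change from 0 to 10 min correlated across genes with that of the other strains at -0.57 and -0.34 in replicates 1 and 2 and at 0.46 in replicate 3. With 1 array at 0 min, whose spread is taken from the other groups and whose median SE is 0.469 in place of 0.336, 90 genes differed from WT with replicate 1, 470 with replicate 2 and 40 with replicate 3. With replicate 3 alone PHO84 (2.54, adjusted p = 0.16) and PRM7 (2.13, adjusted p = 0.17) had a similar size and did not pass.

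At 60 min of 3AT each deletion strain was also compared with its own 0 min arrays. MMP1, PIC2 and REE1 changed in the same direction in 6 of the 7 strains each, MMP1 by 1.77 to 3.13 and REE1 by 1.5 to 2.39 in the strains where they passed, chosen after their values were seen. PHO84 rose by 4.14 ± 0.66 in gcn4, 2.84 ± 0.59 in leu3, 3.42 ± 0.59 in gat1 (259 ± 74.7 to 2880 ± 348, n = 3 each, limma adjusted p = 7.1e-05), 2.22 ± 0.66 in gat1gcn4 and 4.19 ± 0.59 in gcn4leu3. Its value was 0.77 in WT and -0.23 in gat1leu3, where it did not pass. Of 13 phosphate regulon genes, 5 rose and 1 fell in gat1 (8 adjusted over the list alone, median 0.75, camera adjusted p = 2.1e-07), 5 rose in gcn4leu3 (7, median 0.86, 1.7e-07) and 3 rose in gat1gcn4 (4, median 0.50, 0.00024).

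Arginine genes also fell at 60 min in gat1, 6 of 7 (6 adjusted over the list alone, median -2.20, camera adjusted p = 9.6e-15). In gat1leu3 7 of 7 fell (7 adjusted over the list alone, median -1.81, camera adjusted p = 1.5e-10). With replicate 3 alone at 0 min the list kept its call there (median -1.03, adjusted p = 0.014), while ARG1, ARG3, ARG7 and ARG8 had -1.55, -1.53, -1.03 and -0.39 and none of them passed (adjusted p = 0.11, 0.39, 0.46 and 0.86). Vitamin B6 genes rose in the 3 strains without GCN4 (2 of 2 in each, also adjusted over the list alone, medians 1.85, 2.57 and 1.59 in gcn4, gat1gcn4 and gcn4leu3, camera adjusted p = 3.3e-05, 7.3e-08 and 0.00016). Retrograde genes rose there too (3, 1 and 5 of 7, with 6, 4 and 6 adjusted over the list alone, medians 1.28, 1.14 and 2.07, camera adjusted p = 6.6e-10, 5.7e-05 and 1.3e-13), with IDH1, isocitrate dehydrogenase, at 2.57 ± 0.41 in gcn4leu3. Aromatic genes fell in gat1 (2 of 14, 6 adjusted over the list alone, median -0.59) and gat1leu3 (7 of 14, 10, median -0.91), with camera adjusted p = 3.6e-05 and 1.3e-07, and in gat1leu3 with replicate 3 alone at 0 min the median was -0.25 and the call was lost (adjusted p = 0.20). G2/M genes fell in gat1 (3 of 7, 4 adjusted over the list alone, median -0.94, camera adjusted p = 5.6e-06), CLB1 by 2.30 ± 0.43. With the preset correlation 20, 13, 20, 12, 13 and 16 lists passed in gcn4, leu3, gat1, gat1gcn4, gcn4leu3 and gat1leu3, and with an estimated one 2, 0, 4, 3, 3 and 2, those named so far for the 60 min responses. Leu3 targets had medians of -0.46 in leu3 (none of 7 passed, 3 adjusted over the list alone, camera adjusted p = 0.19), -0.18 in gcn4leu3, where the test pointed upward (none, 1, 0.96), and -1.02 in gat1leu3 (3 fell, 4, 0.00085, adjusted p = 0.078 with an estimated correlation). There BAT1 fell by 2.17, and had -1.40 with replicate 3 alone at 0 min (adjusted p = 0.18). Nitrogen catabolite repressed genes had medians of -0.52 in gat1 (3 of 22 fell, 7 adjusted over the list alone, camera adjusted p = 5.5e-05), DAL3 by 2.34, -0.32 in gat1gcn4 (2, 3, 0.0035) and 0 in gat1leu3 (1 rose, 1, 0.93), and the first 2 calls were lost (adjusted p = 0.092 and 0.25 with an estimated correlation).

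Among the other large changes at 60 min, MET2 rose in leu3 (2.98 ± 0.82) and gcn4leu3 (3.03 ± 0.82), HSP82 in gat1leu3 (3.85 ± 0.67), and SND2 in gat1gcn4 (3.58 ± 0.54). HSP12 fell in gat1 (-4.18 ± 0.82), PHM8 in gcn4 (-3.45 ± 0.50), YNL134C in leu3 (-3.46 ± 0.52), the fatty acid desaturase gene OLE1 in gcn4leu3 (-3.44 ± 0.59), AGP1 in gat1gcn4 (-3.16 ± 0.45) and NPL3 in gat1leu3 (-3.54 ± 0.64). The numbers of genes that rose and fell were 36 and 55 in gcn4, 29 and 82 in leu3, 33 and 83 in gat1, 101 and 29 in gat1gcn4, 45 and 59 in gcn4leu3, and 209 and 198 in gat1leu3. Omitting 1 array, given in brackets by time and replicate, gave 20 (60 min 1) to 246 genes (0 min 3) in gcn4, 51 (0 min 1) to 129 in leu3, 60 (0 min 1) to 111 in gat1, 7 (0 min 3) to 233 (60 min 3) in gat1gcn4, 27 (0 min 2) to 205 (0 min 3) in gcn4leu3 and 105 (0 min 2) to 574 (0 min 3) in gat1leu3. The 60 min arrays of gat1gcn4 correlated across genes at 0.05, 0.07 and 0.59 with the 60 min profile of the other strains and at 0.18, 0.09 and 0.63 with an earlier one, of 30, 30 and 45 min. Median centring gave 45 and 73 in leu3 and 49 and 67 in gat1. With the replicate block 235 genes were called in leu3 and 328 in gcn4leu3. Near-zero readings on single arrays enter 46 of the 130 calls in gat1gcn4, SND2 among them, 68 of 407 in gat1leu3 and 18 of 111 in leu3, and without such arrays 10, 44 and 71 genes were called. With 1 array at 0 min the gat1leu3 count was 97 for replicate 1, 488 for replicate 2 and 64 for replicate 3, where HSP82 did not pass (2.51, adjusted p = 0.19).

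The difference between each strain's 60 min response and that of WT was then tested itself. In gcn4 the arginine list moved upward relative to WT by a median of 2.08 (2 of 7 rose, 5 adjusted over the list alone, camera adjusted p = 3.9e-11), in gat1gcn4 by 1.5 (2 of 7, 5, 3.4e-06) and in gcn4leu3 by 1.74 (2 of 7, 5, 2.6e-09). ARG4 differed by 2.46 ± 0.58 in gcn4, where its signal went from 999 ± 130 to 2120 ± 24 (n = 3 and 2, limma adjusted p = 0.045), and by 2.70 ± 0.54 in gcn4leu3. In gcn4, ARG1 (2.25 ± 0.54), YHB1 (2.23 ± 0.53) and AAT2 (aspartate aminotransferase, 1.81 ± 0.41) also responded higher, and BAG7 (-3.07 ± 0.74), YDR222W (-3.03 ± 0.59), TSA2 (-2.94 ± 0.68) and TOS3 (-2.53 ± 0.60) lower. With median centring ARG4, ARG1, YHB1 and AAT2 had 2.32, 2.11, 2.09 and 1.67 and lost their calls (adjusted p = 0.11, 0.14, 0.11 and 0.11), so that 0 genes were higher by limma (360 at an unadjusted p under 0.05 in either direction without centring) and 4 lower. With quantile normalization AAT2 alone stayed higher (1.79, adjusted p = 0.046). In gcn4leu3, PHO84 (3.42 ± 0.83), the Pho85 cyclin gene PCL5 (2.89 ± 0.68), ARO5 (2.74 ± 0.58) and ECM13 (2.67 ± 0.60) responded higher and COX26 lower (-2.78 ± 0.62). The phosphate list was higher in gat1 (median 1.01), gat1gcn4 (0.73) and gcn4leu3 (0.99), with camera adjusted p = 3.8e-06, 0.0012 and 4e-06 and 0, 0 and 1 of 13 genes rising by limma (5, 0 and 4 adjusted over the list alone).

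Other differing lists were aromatic (median 0.73, none of 14 passed, 5 adjusted over the list alone, camera adjusted p = 6.4e-06) and glutamate (0.69, none of 6, 1, 0.0044) in gcn4. Others were zinc in gat1 (1.02, none of 6, 2, 0.00022), vitamin B6 in gat1gcn4 (2.04, 1 of 2, 2, 3e-04) and retrograde in gcn4leu3 (0.62, IDH1 of 7, 3, 0.00034). In all, 4 genes responded higher and 4 lower in gcn4, 58 and 3 in gat1gcn4, and 9 and 1 in gcn4leu3. Limma called 0 in leu3 (203 at an unadjusted p under 0.05), 0 in gat1 (284) and 0 in gat1leu3 (496). Omitting 1 array gave 4 (0 min 3) to 146 (0 min 1) in gat1gcn4, 2 (0 min 2) to 14 in gcn4leu3, and at most 21 (60 min 1) in leu3, 1 (WT 60 min 3) in gat1 and 187 (0 min 3) in gat1leu3, with the array in brackets by time and replicate. Leu3 targets had medians of -0.25 in leu3 and 0.14 in gcn4leu3, and nitrogen catabolite repressed genes 0.21 in gat1 and 0.10 in gat1gcn4 (none passed, 0 adjusted over the list alone, camera adjusted p = 0.95, 0.32, 1 and 0.70). In gat1leu3 the lists had -0.96 and 0.52 (none passed, 3 and 2 adjusted over the list alone, camera adjusted p = 0.044 and 0.0035) and lost their calls (adjusted p = 0.35 each with an estimated correlation), with -0.55 and -0.11 from replicate 3 alone at 0 min. In gat1gcn4, 36 of 61 calls involve near-zero readings on single arrays, among them the increases of CWP2 (4.49 ± 0.87), RPS21B (4.25 ± 0.91), FUN12 (3.94 ± 0.74) and SOD1 (3.78 ± 0.84). In this order they had values of 0, -0.68, 0.53 and -0.50 without the 0 min array of replicate 3, and none of the 4 passed. MET14 (-3.16 ± 0.81), MMP1 (-2.87 ± 0.75) and BIO2 (-2.32 ± 0.60) responded lower, with values of -4.29, -4.13 and -2.70 without that array, where BIO2 no longer passed (adjusted p = 0.093). Without the 0 min array of replicate 1 they had -2.03, -1.61 and -1.93, and none of the 3 passed (adjusted p = 0.42, 0.57 and 0.17). In gat1gcn4 the calls also ended for ARG4 without replicate 3 of 0 min (2.09, adjusted p = 0.27), for ARG1 without replicate 1 (1.53, adjusted p = 0.30), and for SNZ1 without replicate 1 (2.02, adjusted p = 0.097) or 3 (2.23, adjusted p = 0.23). The vitamin B6 list lost its call without replicate 1 (median 1.82, adjusted p = 0.077). For gcn4 a pseudocount of 1 left 1 call, YDR222W. Leaving out gcn4 0 min replicate 3 gave 66 genes, and leaving out replicate 1 or 2 of that time gave 0 by limma (308 and 230 at an unadjusted p under 0.05).

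**Figure D3:**
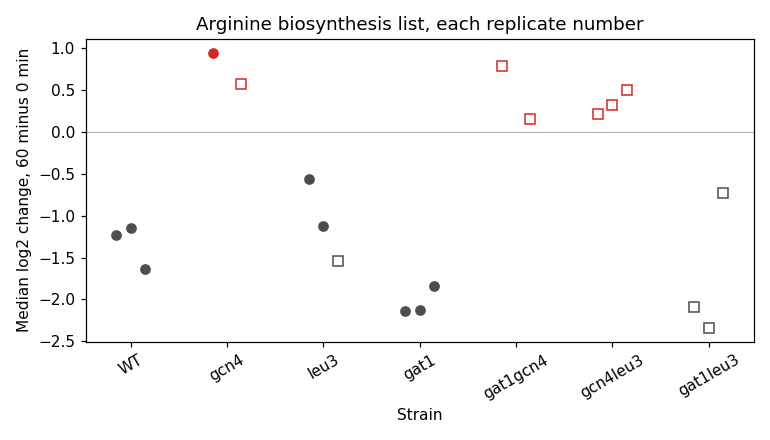
Median log2 change of the arginine list from 0 to 60 min (y axis) for each replicate number (points) of each strain (x axis); red marks strains without GCN4 and dark strains with it, filled circles arrays deposited scaled and open squares arrays deposited unscaled. The points without GCN4 lie between 0.16 and 0.95, and those with it between -2.34 and -0.56.

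Whether a deletion changed expression by the same log2 amount with and without the other was tested at 60 min. In gat1leu3 PHO84 lay 5.80 ± 0.83 below the sum of both single deletions (signal 466 ± 476 in gat1leu3 and 2880 ± 348 in gat1, n = 3 each, value -5.80, limma adjusted p = 1.5e-06), and SPL2, an inhibitor of low-affinity phosphate uptake, had -2.67 ± 0.53. Of 13 phosphate genes 4 were lower than the sum (9 adjusted over the list alone, median -1.49, camera adjusted p = 5.4e-14). In gat1gcn4 the siderophore genes FIT2 (5.28 ± 1.11) and FIT3 (4.37 ± 0.99), MNC1 (2.75 ± 0.57) and SNZ1 (2.36 ± 0.57) lay above the sum, and PHO84 (-4.15 ± 0.88), SNR14 (-4.11 ± 0.93) and the tRNA gene YNCD0028W (-4.09 ± 0.92) below it. The vitamin B6 pair was above the sum in gat1gcn4 (median 2.29, 1 of 2 passed, 2 adjusted over the list alone, camera adjusted p = 5.7e-05) and gcn4leu3 (1.91, none of 2, 2, 0.0001). Counts above and below were 11 and 15 in gat1gcn4, 1 and 0 in gcn4leu3, and 3 and 15 in gat1leu3 (18 and 15 in gat1gcn4 with quantile normalization, 4 and 7 in gat1leu3 with median centring). The gene in gcn4leu3 was the auxotrophic marker URA3 (4.74 ± 0.75, limma adjusted p = 3.2e-05). The median over all genes was -0.13 in the gat1leu3 contrast. Strain and scaling class cannot be told apart here either. With the class as a block, under the same assumption of 1 unscaled batch, 70 genes were called in gat1gcn4 and 4 in gcn4leu3, where omissions of 1 array gave 1 to 20, the highest without leu3 replicate 1. Of the 15 genes below the sum in gat1gcn4, 11 were small RNA genes, whose signal differed between sets of arrays, and 1-array omissions gave 6 to 40 genes there, the lowest without gcn4 replicate 1 and the highest without gat1gcn4 replicate 3. In gat1leu3 such omissions gave 3 to 47, the lowest without gat1 replicate 1 and the highest without gat1leu3 replicate 1, and 11 genes were called without arrays holding near-zero readings and 9 with these readings left out.

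In the met31 strain, with no replicates, the sulfur and methionine list had median changes of 0.18 at 10 min, 0.59 at 20 min, 0.51 at 30 min, 0.99 at 45 min and 1.15 at 60 min. The WT medians were 0.33, 0.84, 0.74, 0.82 and 1.15 at these times. The arginine list stood at -1.79 at 60 min in met31. Each change is taken from the single met31 0 min array, 1 of the 6 arrays with near-zero readings (22 probe sets, 0 of them in the sulfur or arginine list). A difference between the strains was not tested.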

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

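The tests of explanations for the 3 patterns weighed here, and the comparisons at 20 min, were chosen only after the results were seen; the counts over other splits of the arrays were planned. Tested with limma, 60 min responses differed from that of WT at 8 genes in gcn4, 61 in gat1gcn4 and 10 in gcn4leu3. At 20 min the same test gave 15 genes in gcn4, 5 in leu3, 4 in gat1, 86 in gat1gcn4, 10 in gcn4leu3 and 76 in gat1leu3. Without arrays holding near-zero readings the 20 min counts were 10 in gat1gcn4 and 10 in gat1leu3; without gat1gcn4 0 min replicate 3 the first was 9, and with 1 gat1leu3 array at 0 min the second was 37, 399 and 1 for replicates 1, 2 and 3. At 60 min 26 genes in gat1gcn4, 1 in gcn4leu3 (the marker URA3) and 18 in gat1leu3 departed from the sum of both single deletions. Gene lists whose response differed from WT, by their median difference, were arginine (2.08), aromatic (0.73) and glutamate (0.69) in gcn4 and zinc (1.02) and phosphate (1.01) in gat1. In gat1gcn4 they were arginine (1.5), vitamin B6 (2.04) and phosphate (0.73), and in gcn4leu3 arginine (1.74), phosphate (0.99) and retrograde (0.62). In data that entered no comparison, the library labelled gcn4 90 min replicate 3 had a GCN4 signal of 2290, where the next highest in that strain was 434.

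On 6 arrays abundant genes read near 0, with 32 probe sets on leu3 60 min replicate 3, 50 on gat1gcn4 0 min replicate 3, 37 on gcn4leu3 10 min replicate 3, 91 on gat1leu3 0 min replicate 2, 44 on gat1leu3 60 min replicate 3 and 22 on met31 0 min replicate 1. The tables argue against degraded RNA on 5 of them, whose actin 3'/5' ratios were at most 1.63 against a 90th percentile of 1.98 on arrays without such readings, and leave it open on leu3 60 min replicate 3, with 2.24, a ratio exceeded on 9 arrays without such readings. The deletion and the time stay untested, because such readings were defined by high values on every other array of the strain, so that the replicates' 1.01 times the signal of those arrays decides nothing. Local damage or uneven hybridisation is a candidate explanation: on 5 of the 6 arrays the lost probe sets lay closer together in running number than in at least 95 of 100 random draws (median gaps of 3, 12, 50.5, 2 and 56). On gat1leu3 0 min replicate 2 they did not (gap 69.5 against 60 in random draws, 93 of 100 draws as small), and for that array the question stays open.

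In gat1leu3 replicates 1 and 2, the change from 0 to 10 min ran against that of the other strains, with correlations across genes, which are not independent, of -0.57 and -0.34, while 17 pairs of same-numbered arrays of the other strains had 0.01 to 0.69. The tables argue against the deletion of GAT1 and LEU3, since replicate 3 of the same strain had 0.46, and against the near-zero readings, since replicate 2 without them had -0.43. An exchange of the arrays labelled 0 and 10 min in both replicates is a candidate explanation: the higher of the 2 correlations, -0.34, lies below every other pair, and the 4 arrays matched the profile of the other time best (correlations of 0.58 to 0.84, against -0.16 to 0.05 with their own). Every 0 min array of the other strains matched its own label, but leu3 replicates 1 and 2 matched the next later time from 10 to 45 min (own-time values of 0.15 to 0.57). In gat1gcn4 6 of 16 arrays matched their label and none of those at 60 min did, and the gap of its 10 min replicate 3 (0.78 with 0 min, 0.13 with its own) was as wide as the narrowest of the 4 (0.58 and -0.06); the labels were kept, as values alone do not set a group.

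The arginine list fell at 60 min in strains with GCN4 and not in those without. In leu3 0 lists were called with an estimated correlation. The tables argue against the deposited scale, since among unscaled arrays alone same-numbered pairs without GCN4 lay 2.22 above those with it, and against signals near background, since the members had a median signal of 534 at 0 min in strains without GCN4. Of the unscaled pairs with GCN4, gat1leu3 replicates 1 and 2 (-2.09 and -2.34) carry the doubtful 0 min label, and the other 2 had -1.54 and -0.73 against 0.16 to 0.79 without GCN4; in scaled arrays 8 pairs with GCN4 had a median of -1.44 and 1 without had 0.95. The GCN4 genotype and the list's lower start at 0 min in strains without it cannot be told apart. That only the real 1 of 35 splits of the 7 strains gave a difference as large as 2.12 decides nothing, since the pattern was stated as this separation.

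For the WT time course, 1 of 100 splits of the arrays, the real one, gave 405 genes and the highest other gave 130, so that chance can be excluded. Comparisons of 3 against 3 arrays have 10 splits, too few for a share under 0.05, with a real count and highest other of 71 and 0 for WT at 10 min, 125 and 0 at 20 min, 83 and 4 at 30 min, 59 and 0 at 45 min, 46 and 0 at 60 min, 42 and 0 at 90 min, and 70 and 1 at 120 min. For baselines they were 272 and 232 in gcn4, 10 and 0 in leu3, 5 and 0 in gat1, 191 and 1 in gcn4leu3, and 376 and 200 in gat1leu3. The gcn4 split with 232 genes put WT replicate 1 with gcn4 replicates 1 and 2, against an unscaled gcn4 replicate 3; with scaled arrays alone the baseline count was 1035. That of gat1leu3 with 200 put WT replicate 3 with gat1leu3 replicates 1 and 2, the arrays whose 0 min label is in doubt. For 60 min responses they were 111 and 44 in leu3, 116 and 2 in gat1, 104 and 1 in gcn4leu3, and 407 and 509 in gat1leu3, where 2 of 10 splits gave as many. The split with 509 set replicate 3 at 0 min with replicates 1 and 3 at 60 min, again parting 0 min replicates 1 and 2 from replicate 3, which points to a structure of the samples other than time.

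For response differences limma called 0 really and at most 0 in leu3, 0 and 0 in gat1, and 0 and 3 in gat1leu3 (10 of 10 splits as large in each, 203, 284 and 496 genes at an unadjusted p under 0.05), and 10 and 0 in gcn4leu3. For the departure from the sum in gat1leu3, 12 of 100 splits gave as many as the real 18 genes and the highest gave 84, so that chance cannot be excluded, and a split with several times the real count points to a structure of the samples.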

How the results depend on the processing

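The number of arrays and the signal over background limit these results: the median SE of 0.336 for 3 against 3 arrays left 2-fold changes partly undetected, and genes near the array floor (median 21.34) change little on the log2(signal + 16) scale. Alternatives on scaling class, deposited values, near-zero readings, RNA quality, single replicates and protein-coding genes were chosen after seeing the data; the others were fixed before the data were examined. Below, baselines, responses and differences are the counts of genes for each strain at 0 min against WT, at 60 min against 0 min, and for that change against WT's, WT responses stand in order of time from 10 to 120 min and unnamed strains in the order gcn4, leu3, gat1, gat1gcn4, gcn4leu3 and gat1leu3, and sums are the counts of genes that departed from the sum of both single deletions. Only counts that moved by over 1.5 times are given, numbers in brackets beside a 0 are genes at an unadjusted p under 0.05, and the cause was not tested. No filter, the stricter filter, eBayes without trend and a 2-fold minimum moved no count by that much. Of 268 list calls in baselines, responses, differences and WT at 60 min with the preset correlation, 66 were made with the estimated one, where 15 of the 102 list results reported lost their call.

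With quantile normalization, differences gave 5 in gcn4 and 2 in gat1leu3. With median centring, differences gave 4 in gcn4 and 1 in gat1leu3 and sums gave 11 in gat1leu3. With a pseudocount of 1, differences gave 1 in gcn4. With a pseudocount of 64, differences gave 30 in gat1gcn4 and 2 in gat1leu3 and sums gave 9 in gat1leu3. With array quality weights, WT responses gave 940, 723, 270, 560, 472, 314 and 599, and the time course 1838. Baselines gave 1498 in gcn4, 278 in leu3, 68 in gat1, 117 in gat1gcn4 and 1226 in gcn4leu3. Responses gave 369, 369, 241, 74, 1246 and 128. Differences gave 360 in gcn4, 47 in leu3, 35 in gat1, 725 in gcn4leu3 and 46 in gat1leu3. Sums gave 141, 28 and 39. Over all probe sets, baselines gave 8 in gat1, differences gave 1 in gat1 and sums gave 11 in gat1leu3. In fits of only the strains compared, WT responses gave 162, 332, 203, 162, 120, 126 and 203, and the time course 650. Baselines gave 23 in leu3, 24 in gat1 and 442 in gcn4leu3. Responses gave 37 in leu3, 238 in gat1, 2 in gat1gcn4, 474 in gcn4leu3 and 101 in gat1leu3. Differences gave 25 in gcn4, 13 in gat1, 6 in gat1gcn4, 63 in gcn4leu3 and 5 in gat1leu3. Sums gave 2 in gcn4leu3. With the replicate block, WT responses gave 140, 300, 226, 148, 105, 100 and 232, and the time course 902. Baselines gave 18 in leu3. Responses gave 187, 235, 245, 244, 328 and 697. Differences gave 26 in gcn4, 5 in gat1, 105 in gat1gcn4, 26 in gcn4leu3 and 32 in gat1leu3. Sums gave 32 in gat1leu3. With the replicate block as a random effect, WT responses gave 129, 261, 208, 132, 99, 90 and 194, and the time course 829. Baselines gave 17 in leu3. Responses gave 169, 225, 234, 219, 271 and 685. Differences gave 24 in gcn4, 4 in gat1, 99 in gat1gcn4, 21 in gcn4leu3 and 7 in gat1leu3. Over the mean of 20 to 60 min, differences gave 47 in gcn4, 1 in leu3, 3 in gat1 and 137 in gat1leu3. By an F-test over 10 to 60 min, differences gave 80, 13, 31, 150, 55 and 21.

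With the scaling class as a block, baselines gave 483 in gcn4, 34 in leu3, 525 in gat1gcn4 and 591 in gcn4leu3, differences gave 2 in gat1leu3 and sums gave 70 in gat1gcn4 and 4 in gcn4leu3. In scaled arrays alone, WT responses gave 235, 372, 270, 206, 152, 151 and 289, and the time course 993. Baselines gave 1035 in gcn4, 84 in leu3 and 29 in gat1. Responses gave 365 in gcn4, 232 in leu3 and 321 in gat1. Differences gave 204 in gcn4, 11 in leu3 and 17 in gat1. In unscaled arrays alone, where gcn4 and leu3 have 1 array in each group and the double deletions supply the spread, responses gave 0 in gcn4 (189), 73 in leu3, 51 in gat1gcn4, 54 in gcn4leu3 and 219 in gat1leu3 by limma. In the deposited values without rescaling, WT responses gave 6, 12, 6, 3, 4, 2 and 4, and the time course 30. Baselines gave 35, 6, 1, 4773, 5189 and 5344. Responses gave 3, 2, 1, 0 (30), 0 (28) and 0 (49) by limma. Differences gave 1 in gcn4, 0 in gat1gcn4 (15) and 0 in gcn4leu3 (13) by limma. Sums gave 0 in gat1gcn4 (326) and 0 in gcn4leu3 (38) by limma. Without the arrays holding near-zero readings, baselines gave 80 in gat1leu3, responses gave 71 in leu3, 10 in gat1gcn4 and 44 in gat1leu3, differences gave 6 in gat1gcn4 and sums gave 11 in gat1leu3. With near-zero readings left out, responses gave 65 in gat1gcn4, differences gave 11 in gat1gcn4 and sums gave 9 in gat1leu3. Without arrays of an actin ratio above 3, differences gave 26 in gat1leu3 and sums gave 51 in gat1leu3. In replicates 1 and 2 alone, WT responses gave 192, 384, 601, 185, 149, 164 and 271, and the time course 1319. Baselines gave 1000, 129, 46, 750, 530 and 1098. Responses gave 518, 383, 381, 392, 586 and 868. Differences gave 270, 42, 63, 227, 195 and 366. Sums gave 353, 92 and 312. In gat1leu3 with 1 array at 0 min, assumed to vary like the other groups, baselines were 90 and 40 and responses 97 and 64 for replicates 1 and 3, and differences 10 and 334 for replicates 1 and 2. Among protein-coding genes, sums gave 15 in gat1gcn4.

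Leaving out 1 array at a time, which in a group of 2 leaves 1 array that is assumed to vary like the other groups, moved counts as follows, in order of replicate. Numbers after a time or strain are replicates, a time without a strain is of the strain compared, and for sums the arrays are of 60 min. WT at 10 min gave 34, 35 and 37 without each 0 min array and 31, 26 and 42 without each 10 min array. WT at 20 min gave at most 126, with 58, 58 and 82 without each 0 min array and 62 and 69 without 20 min 1 and 2. WT at 30 min gave 44, 49 and 53 without each 0 min array and 55 and 226 without 30 min 2 and 3. WT at 45 min gave at most 40, with 30 and 27 without 0 min 1 and 2 and 38, 35 and 39 without each 45 min array. WT at 60 min gave at most 33, with 23 and 26 without 0 min 1 and 2 and 30 without 60 min 2. WT at 90 min gave 14, 13 and 25 without each 0 min array and 22, 12 and 26 without each 90 min array. WT at 120 min gave at most 70, with 35, 24 and 28 without each 0 min array and 27 and 35 without 120 min 2 and 3. The time course ranged from 315 to 527. The gcn4 baseline was 133, 101 and 672 without each 0 min array. The leu3 baseline was at least 7, with 16 without 0 min 1. The gat1 baseline was at most 6, with 3 without 0 min 3. The gat1gcn4 baseline ranged from 173 to 269. The gcn4leu3 baseline was at most 272, with 123 without WT 0 min 1 and 100 and 110 without 0 min 1 and 2. The gat1leu3 baseline was 192 and 193 without WT 0 min 1 and 2 and 66 and 567 without 0 min 2 and 3. The gcn4 response was 33, 40 and 246 without each 0 min array and 20 without 60 min 1. The leu3 response was at most 129, with 51 without 0 min 1 and 59 without 60 min 3. The gat1 response was at most 111, with 60, 62 and 70 without each 0 min array and 65 and 70 without 60 min 1 and 2. The gat1gcn4 response was 199 and 7 without each 0 min array and 82, 84 and 233 without each 60 min array. The gcn4leu3 response was 47, 27 and 205 without each 0 min array and 39, 47 and 42 without each 60 min array. The gat1leu3 response was at most 574, with 105 without 0 min 2 and 217 without 60 min 3. The gcn4 difference was 1, 1 and 2 without each WT 0 min array, 2, 1 and 1 without each WT 60 min array, 0 (308), 0 (230) and 66 without each 0 min array, and 1 without 60 min 1, by limma. The leu3 difference was at least 0, with 21 and 4 without 60 min 1 and 2. The gat1 difference was at least 0, with 1 without WT 60 min 3. The gat1gcn4 difference was 40 without WT 0 min 2, 146 and 4 without each 0 min array, and 39 without 60 min 1. The gcn4leu3 difference was at most 14, with 5 without WT 0 min 3, 6 and 2 without 0 min 1 and 2, and 6 and 3 without 60 min 1 and 3. The gat1leu3 difference was at least 0, with 2 without WT 0 min 3, 2 without WT 60 min 3, 82 and 187 without 0 min 1 and 3, and 25 and 22 without 60 min 1 and 2. The gat1gcn4 sum was 13 without WT 2, 6 without gcn4 1, 10 and 14 without gat1 1 and 2, and 11, 9 and 40 without each gat1gcn4 array. The gcn4leu3 sum was at least 1, with 4 without gcn4 3 and 20 and 6 without leu3 1 and 2. The gat1leu3 sum was 6, 6 and 7 without each WT array, 33 without leu3 1, 3, 7 and 10 without each gat1 array, and 47, 46 and 5 without each gat1leu3 array.

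Scaling changed the share of rising genes by over 10 points in further splits, given as rising and falling genes. Median centring gave 6 and 7 for the leu3 baseline (3 and 7 as reported). Quantile normalization gave 43 and 24 for WT at 10 min (36 and 35), 87 and 44 at 20 min (69 and 56) and 25 and 46 at 120 min (17 and 53), 1 and 4 for the gcn4 difference (4 and 4), and 4 and 10 for the gat1leu3 sum (3 and 15). At 20 min the split was 49 and 36 in gat1leu3 with median centring (53 and 23) and 2 and 3 in gat1 with quantile normalization (1 and 3). For GCN4 deletion at 60 min median centring gave 5 and 6 in WT (7 and 4), and quantile normalization 8 and 8 in WT and 99 and 70 in leu3. For LEU3 deletion it was 3 and 23 in gcn4 with median centring (8 and 25) and 48 and 80 in gat1 with quantile normalization (19 and 102).

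The values of 419 named-gene results kept their direction in every alternative but those given next. In the deposited values the sign was opposite for the gat1leu3 baselines of HXT6 (-0.38), PHO84 (-0.39), PRM7 (-0.90) and HXT7 (-0.96), and for RAX2 (-0.81) and MMR1 (-0.51) against the sum in gat1leu3. It was also opposite for HSP26 (-0.11) with GCN4 deleted in gat1, for NTH1 with GCN4 deleted in leu3 (-0.23) and gat1 (-1.24), and for the lists of citric acid cycle genes at baseline in gcn4 (-0.45) and stress genes at baseline in gcn4leu3 (-0.57). For the gat1gcn4 difference, CWP2, RPS21B and SOD1 had values of 0, -0.68 and -0.50 without gat1gcn4 0 min replicate 3, without arrays holding near-zero readings and with these readings left out, and -0.74, -0.85 and -0.57 in replicates 1 and 2 alone, where FUN12 had -0.02. With gat1leu3 at 0 min from replicate 3 alone the sign turned for its nitrogen catabolite list at baseline (0.18), GAP1 (0.16) and MEP2 (0.18) in it, and the list's difference (-0.11). Over all omissions of 1 array these values ran from 0 to 8.98 for CWP2, -0.68 to 9.18 for RPS21B and -0.50 to 8.06 for SOD1, each highest without gat1gcn4 0 min replicate 1. Gene calls were lost or reversed for 304 of 419 results in the deposited values, 50 of 419 in fits of only the strains compared, 57 of 129 without arrays holding near-zero readings, 39 of 85 in unscaled arrays alone, 30 of 43 with gat1leu3 at 0 min from replicate 3 alone, 32 of 419 with near-zero readings left out, 6 of 55 without high actin ratios, 1 of 231 in scaled arrays alone, and 23 or fewer under each other setting but omissions of 1 array. The histidine list in WT at 60 min lost its call with array weights (adjusted p = 0.059), median centring (0.051), replicates 1 and 2 alone (0.10) and deposited values (0.21). With weights the nitrogen catabolite list lost it at baseline in gat1 (0.052), and with deposited values the glutamate list did in WT at 60 and 90 min (0.053 and 0.065) and at baseline in gcn4 (0.067). In gat1leu3 the nitrogen list lost it at baseline with deposited values (0.29), Leu3 targets at baseline in replicates 1 and 2 alone (0.14), both as differences without near-zero arrays (0.063 each), and Leu3 targets as a difference also with quantile normalization (0.13), median centring (0.060) and without high actin ratios (0.16). Over omissions of 1 array, 203 of 419 gene results and 10 of 102 list results lost their call at least once. The replicate block ended the call of the histidine list in WT at 60 min (adjusted p = 0.051 with limma's camera) and changed no other call of a named gene or list.

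Replicate numbers were not taken as pairing the samples in the other comparisons, where at least 1 correlation of same-numbered arrays was 0.1 or lower (from -0.20 for the gat1 response) or fewer than 3 pairs existed, as for the responses of gcn4 (0.28 and 0.34) and gat1gcn4 (0.21 and 0.29). The list tests were not run with the replicate block as a random effect.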

Other observations

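The comparisons and the genes named below were chosen only after results were seen. SRX1 rose 20 min after 3AT in WT from a signal of 118 ± 36.3 to 5490 ± 1500 (SD, n = 3 each). Its response was lower in each of the 6 deletion strains with replicates. The difference from WT was -3.72 ± 0.68 (SE) in gcn4 (limma adjusted p = 0.0016), -4.57 ± 0.68 in leu3 (5.3e-06), -4.90 ± 0.72 in gat1 (3.6e-06), -5.77 ± 0.72 in gat1gcn4 (9.5e-09), -3.89 ± 0.68 in gcn4leu3 (0.00019) and -4.60 ± 0.68 in gat1leu3 (4.2e-06). TRR1 responded less in 5 of the 6 strains, with -1.64 ± 0.33 in gat1 and -1.78 ± 0.33 in gat1gcn4. It missed the threshold in leu3 (-1.29 ± 0.32, limma adjusted p = 0.069). CCC2, a copper transporter, and YAT2 responded less in 3 strains each. With gat1leu3 at 0 min from replicate 3 alone, SRX1 kept its call there (-4.88, adjusted p = 0.00036) and TRR1 (-1.33, adjusted p = 0.41), CCC2 (-2.29, 0.27) and YAT2 (-1.54, 0.86) did not. The oxidative stress list responded less in gcn4 (median -0.86, 4 of 20 genes lower, 7 adjusted over the list alone), leu3 (-1.06, 4, 9), gat1 (-0.79, 2, 5) and gat1leu3 (-0.68, 2, 5), with camera adjusted p of 0.0047, 0.00016, 0.00078 and 0.024 with an estimated correlation. With gat1leu3 at 0 min from replicate 3 alone the list had a median of -0.76 there, and its call was lost (adjusted p = 0.15 with an estimated correlation). For gat1gcn4 (-0.53, 4 lower and 1 higher, 6) and gcn4leu3 (-0.56, 2, 5) the call was lost, with adjusted p = 0.12 and 0.052 with an estimated correlation.

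All 6 differences at 20 min share the WT arrays, so that a chance value there appears in each strain. In 20 simulations of unchanged strains against the same controls, at most 0 genes were called in 3 or more strains (4 observed). In all 6 it was at most 0 (1 observed). A difference of the WT arrays, 3 at each time, from the rest of the study is not excluded. At 20 min the oxidative stress and iron medians of met31 (1 array, not tested), 0.12 and 0.43, were also below WT. In leu3 replicates 1 and 2 the arrays labelled 20 min matched the 30 min profile of the other strains best (correlations across genes of 0.62 and 0.48, against 0.31 in each for their own time), and the leu3 difference was not set against a shift in time. SRX1 kept its sign in every alternative run (-6.79 to -3.21 over the strains). Its call was lost in gcn4 without gcn4 0 min replicate 1 (-3.21, adjusted p = 0.063) and in 5 strains in the deposited values.

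Deletion effects at 60 min were also set in the background of a second deletion. Deleting LEU3 lowered OAC1 (-2.37 in WT, -2.29 in gcn4, -2.80 in gat1), BAT1 (-2.51, -2.79, -2.93), LEU1 (-2.34, -2.45, -3.50) and the mitochondrial dicarboxylate carrier gene DIC1 (-1.87, -3.06, -2.16) in all 3 backgrounds. Leu3 targets had medians of -0.86, -0.97 and -1.17 (3 of 7 lower in each, 3, 3 and 4 adjusted over the list alone), with adjusted p = 2.5e-05, 3.2e-05 and 0.00026 with an estimated correlation. Deleting GCN4 raised the heat shock gene HSP26 (1.93, 2.66 and 2.54 in WT, leu3 and gat1) and the trehalase gene NTH1 (1.71, 1.47 and 1.42), although HSP26 in gat1 and NTH1 in leu3 and gat1 had the opposite sign in the deposited values. The numbers called were 11, 201 and 560 for GCN4, 42, 33 and 121 for LEU3 (WT, gcn4, gat1), and 9, 27 and 139 for GAT1 (WT, gcn4, leu3), where GAT1 itself was the only gene called in all 3 backgrounds. Strain and scaling class are confounded in these counts. Median centring turned 138 genes up and 63 down for GCN4 in leu3 into 73 and 101, and 342 and 218 in gat1 into 234 and 315, and without arrays holding near-zero readings 14 genes were called for LEU3 in WT and 48 in gat1. Deleting GAT1 in WT raised the phosphate list (median 0.77, 3 of 13 rose, 8 adjusted over the list alone, adjusted p = 1.5e-07 with an estimated correlation), and deleting LEU3 raised it in WT (0.57, 1 rose, 4, 0.0019) and lowered it in gat1 (-1.03, 6 fell, 8, 8.4e-05).

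Small RNA genes (156 tested, tRNA, snRNA and other noncoding genes) differed between sets of arrays. Their median signal per array had a median of 88.4 over the 57 double deletion and met31 arrays (57.6 to 334), 252 over the 78 scaled arrays (102 to 611) and 459 over the 16 unscaled arrays of gcn4 and leu3 (208 to 1010). They made up 17 of the genes that fell at baseline in gat1leu3, 12 in gcn4leu3 and 9 in gat1gcn4, and 11 of the 26 genes that departed from the sum in gat1gcn4, of which 15 were called among protein-coding genes alone.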
